A study of Sus scrofa with 95 samples.

How the data were processed

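Poly(A) RNA from 5 organs of 19 pigs was prepared with the Tecan Universal Plus mRNA-Seq kit and sequenced as paired reads on a NovaSeq 6000, 95 libraries in all. The authors deposited one table of expected counts, that is, estimated read counts per Ensembl gene that are not scaled for library size or gene length. The submitters' notes name bcl2fastq, Trim Galore, cutadapt, STAR, Salmon and MultiQC and the Sscrofa11.1 assembly, without versions, and without saying which program made the counts or which annotation release was used. The table holds 35670 genes, of which 17508 have a symbol in it, 223 were named from a gene ID table and 17939 have an ID only. The symbols of 110 genes differ between the table and the ID table, and the table's own symbols are used, including VWF, which the ID table calls ANO2, so its values can belong to either gene. Between 92.7 and 96.6% of the values in a library are whole numbers, and all values were rounded. No genome was at hand, so no positions are given.

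Total counts per library, in units of 1e6, were 20 to 53.6. They averaged 24.8 ± 2.4 (SD) in heart controls, 22.7 ± 1.68 in heart CPB and 23.3 ± 2.41 in heart linrodostat libraries. The 10 most abundant genes took 4.6 to 38% of a library. The precision of a fold change comes from the spread between animals, whose biological coefficient of variation was 0.353 in heart, 0.526 in ileum, 0.365 in kidney, 0.356 in liver and 0.339 in lung.

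Groups follow the labels: control (8 animals), CPB (7) and CPB with linrodostat (4). Sex was near balanced, and the labels of sex were checked against sex-linked genes with 0 mismatches. Within each organ and arm, no library was a copy of another. The animal numbers in the labels were checked across organs: after organ and arm means were removed, libraries of the same animal in 2 organs had median correlations of 0.134 to 0.3 over 10 organ pairs and 13637 genes. All heart libraries bear batch label 2 and all others batch label 1.

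Each organ was analysed apart in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM normalisation, glmQLFit with robust estimation over all 19 libraries, and quasi-likelihood F tests of CPB against control, linrodostat against CPB and linrodostat against control. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in the organ passed. All tests are 2-sided. The difference of the CPB effect between organs was tested with an F test on all 95 libraries. Gene groups were tested with camera (limma 3.58.1) on log2 CPM from voom with a preset correlation of 0.01, for 45 lists that ask for 824 genes, of which 753 are in the table. A list needed 5 tested genes, which left 30 lists in heart, 31 in ileum, 34 in kidney, 33 in liver and 33 in lung, and list p-values were adjusted within organ and comparison. Levels are TMM-normalised CPM, and log2 CPM used a prior count of 2. The IDO1 levels and those of named genes come from the same normalisation.

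The lists, comparisons, thresholds, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule names, in CPB against control and linrodostat against CPB, the 6 highest and 6 lowest log2 fold changes among passing genes with a symbol and a mean of at least 2 CPM in the higher group. It adds up to 3 passing members of each list with the largest change (or the 2 with the smallest p where the list passed and no member did), 7 genes in every organ (IDO1, TDO2, KMO, KYNU, CIRBP, RBM3 and HMOX1), genes shared by all 5 organs, of which there were 0, and the 10 smallest interaction p-values. Not all of these are printed: genes whose call was kept under all the fixed alternatives were preferred as examples, a choice made after the values were seen. Some results are not reported here because they are withheld for evaluation.

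The fixed alternatives were relative log expression size factors, no low-count filter, sex as a covariate, only the 2 groups compared, DESeq2 1.42.0, limma-voom and leaving out each animal in turn. For lists they were also an estimated correlation and fry, and for the interaction test the animal as a block, a fit with a shared correlation per animal, and the test without heart. Added after the data were seen were the shares of ileal and of renal transcripts as covariates, smooth muscle and B cell scores as covariates in ileum, the removal of 2830 genes with at least 10 times their CPB liver level in ileum, the removal of 2 lung libraries, and shared calls in 4 organs without ileum. The share of another organ's transcripts in a library was estimated from marker genes of that organ as a percent of its own profile. For regroupings, 40 groupings of the animals were used for each comparison (24 for the interaction), the real one and others drawn at random with seed 20.

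The procedure was tested on simulated data with known changes. In CPB against control it recovered 61.5, 20.3, 70.4, 64.8 and 58.7% of 2-fold changes in heart, ileum, kidney, liver and lung and 89.1, 70.4, 82.8, 78.3 and 81.7% of 4-fold changes. In linrodostat against CPB it recovered 52.4, 11.9, 42.6, 39.5 and 59.7% of 2-fold changes. Unchanged genes made up 0 to 5.68% of the calls. A simulated shift of the cholesterol list was the only list called among 33. The simulated genes were drawn independently, so this says nothing about false list calls where genes vary together. In the simulated interaction test, 24 of 115 calls were of unchanged genes. Nothing was left out of the main tests.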

Results

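Messenger RNA was sequenced in 5 organs of 19 young pigs: the left ventricle of the heart, the terminal ileum, the kidney cortex, the liver and the right lower lobe of the lung. Cardiopulmonary bypass (CPB) replaces the work of heart and lungs by a machine, and in this model the cooled circulation was also stopped for 75 min (deep hypothermic circulatory arrest). There were 8 anesthesia control animals, 7 animals with CPB and arrest, and 4 animals with CPB, arrest and 75 mg of linrodostat. Linrodostat inhibits IDO1, an enzyme that starts the breakdown of tryptophan to kynurenine. Each animal gave 1 library per organ, 95 in all. Total counts per library, in units of 1e6, lay between 20 and 53.6 (median 35.1). They were 20 to 27.2 in heart, 28.5 to 51.4 in ileum, 25.7 to 42.7 in kidney, 27.8 to 49.7 in liver and 30.1 to 53.6 in lung. Below, a log2 fold change is given ± its standard error, and a level in CPM (counts per 1e6 counts) as mean ± SD over the 8 controls, 7 CPB animals or 4 linrodostat animals. Every p is adjusted unless said otherwise.

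The first question was what CPB with arrest changed in each organ relative to anesthesia alone. More genes passed in liver and kidney than in heart and lung, and none did in ileum. By edgeR, 4151 of 15406 tested genes passed in liver (2404 higher, 1747 lower), 3733 of 17653 in kidney (1992 higher, 1741 lower), 1775 of 14890 in heart (951 higher, 824 lower) and 840 of 17849 in lung (372 higher, 468 lower). In ileum 0 of 17869 genes passed with edgeR, DESeq2 called 16 genes and limma-voom 0. There 932 genes had an unadjusted p under 0.05, near the share of 0.05 that chance alone gives. Of the passing genes, 997 in liver, 1004 in kidney, 456 in heart and 202 in lung differed at least 2-fold. Gene groups were tested with camera on lists fixed in advance, with a small correlation set among their genes. With that correlation estimated from the data 0 lists passed in any organ, and this second adjusted p is given below as "estimated". When the animals were regrouped at random, as many lists passed in 18 of 40 groupings in heart, 20 in ileum, 26 in kidney and 15 in liver, the real one included. In lung they did in the real one alone, by a narrow margin (15 lists, and up to 14 in the others).

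**Figure D1:**
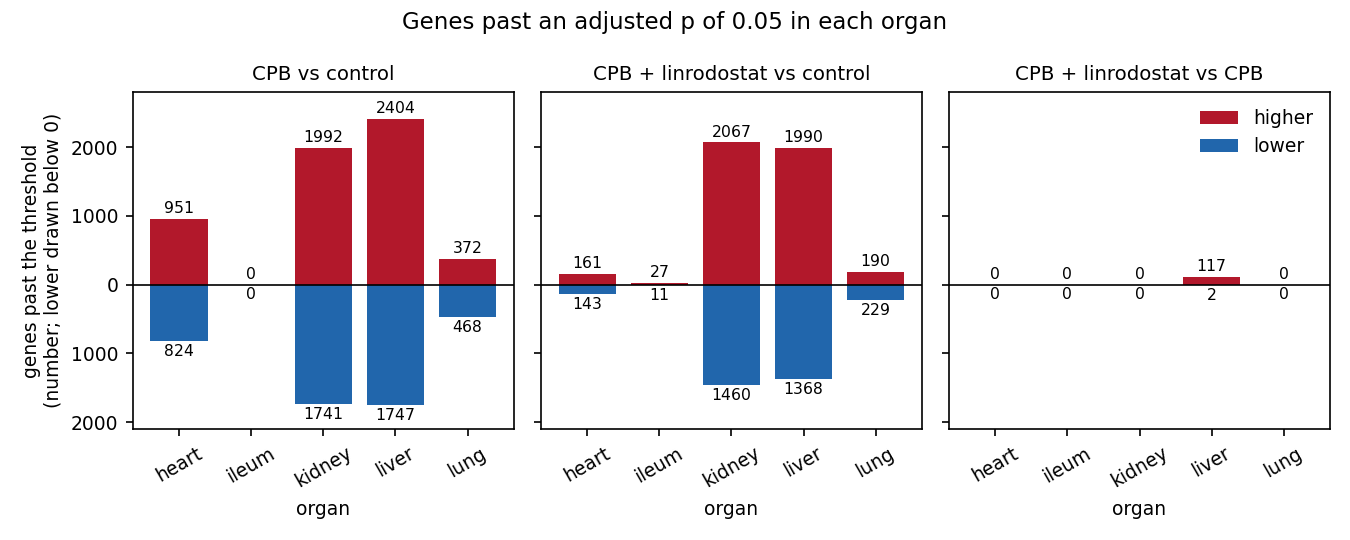
Number of genes past an adjusted p of 0.05 in each organ (higher above, lower below 0) for CPB against control, CPB with linrodostat against control, and CPB with linrodostat against CPB. The first comparison gave 4151 genes in liver and 0 in ileum, and the last gave 119 in liver and 0 in the other organs.

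In the heart, CPB animals had more transcripts of the muscle Z-disc protein PDLIM3, of small heat shock proteins and of genes induced in stressed heart muscle, and fewer of 6 of 20 fatty acid oxidation genes, whose list did not pass. PDLIM3 (ENSSSCG00000015796) rose by 3.63 ± 0.35 on the log2 scale (adjusted p = 2.9e-05), from 5.92 ± 3.29 to 73 ± 26.2 CPM, and all 7 CPB hearts lay above every control heart. KBTBD13 (ENSSSCG00000035667), a muscle protein whose mutations cause a nemaline myopathy, changed by −4.51 ± 0.62 (adjusted p = 0.000147), from 2.07 ± 0.774 to 0.0856 ± 0.13 CPM. The corepressor gene RCOR2 fell by 2.51 on the log2 scale, from 25.7 ± 8.23 to 4.52 ± 2.21 CPM. Actin of heart muscle, ACTC1, rose by 1.26 ± 0.26, and the calcium pump ATP2A2 and its regulator PLN rose by 0.74 ± 0.18 and 0.9 ± 0.19.

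Of 15 cardiac stress genes, 5 rose, 0 fell and 10 did not pass in the heart, and 7 rose when adjusted over the list alone (list adjusted p = 0.000478, estimated 0.227). They included CCN2, a secreted matrix regulator (2.05 ± 0.34, from 20 ± 6.26 to 83.1 ± 59.8 CPM), and XIRP1, a protein of the intercalated disc (1.18 ± 0.19). Among 21 heat shock genes 8 rose and 0 fell, with 9 up when adjusted over the list alone (list adjusted p = 5.05e-05, estimated 0.341). The small chaperone CRYAB (ENSSSCG00000036724) rose by 1.07 ± 0.15, from 555 ± 103 to 1160 ± 244 CPM, HSPB1 by 0.95 ± 0.11 and the cochaperone DNAJA4 by 1.44 ± 0.18. Of 19 IL6-STAT3 response genes 7 rose and 0 fell, both over all genes and adjusted over the list alone (list adjusted p = 0.00609, estimated 0.422), among them TIMP1, an inhibitor of matrix proteases (1.33 ± 0.31), and IL4R (0.94 ± 0.19). All 24 oxidative phosphorylation genes had a fold change above 0 with a median of 0.26, 0 passed singly (0 adjusted over the list alone), and the list passed (adjusted p = 0.000478, estimated 0.863).

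The type I interferon list was lower in CPB hearts, with a median log2 fold change of −1.4 over 23 genes, of which 2 fell and 0 rose, and 14 fell when adjusted over the list alone (list adjusted p = 1.1e-05, estimated 0.863). Control 15 had the highest heart score of this list (2.85) and CPB 2 the lowest of the CPB hearts (−2.06), and the list passed when either 1 was left out. A test on means per animal over 4 organs did not pass (exact permutation p = 0.0824, and 0.298 without both animals). The interferon gamma list had a median of −0.82 over 20 genes with 2 lower and 0 higher, and 4 lower when adjusted over the list alone (list adjusted p = 0.0011, estimated 0.863). IFIT2, an interferon-induced antiviral gene, changed by −1.6 ± 0.45 in heart, a call that was lost with limma-voom, with no low-count filter and without CPB 2 or CPB 19. Of 20 fatty acid oxidation genes 6 fell and 0 rose, and 7 fell when adjusted over the list alone, but the list did not pass (adjusted p = 0.0861). SLC25A20, which carries acylcarnitines into mitochondria, changed by −1.06 ± 0.21 and the peroxisomal enzyme EHHADH by −1.15 ± 0.18. Smooth muscle genes CNN1 (2.04 ± 0.29) and MYLK (1.5 ± 0.25), the hemoglobin scavenger receptor CD163 (1.22 ± 0.31) and the clock gene CRY1 (1.24 ± 0.21) rose. The clock output gene DBP changed by −1.65 ± 0.33. Lists of 14 NRF2 target and metallothionein genes (3 rose, 0 fell, the same counts adjusted over the list alone) and of 27 immediate early genes (4 rose, 0 fell, and 4 rose and 1 fell adjusted over the list alone) passed weakly, at adjusted p = 0.0426 (estimated 0.36) and adjusted p = 0.0433 (estimated 0.863). The NRF2 call ended without control 1, 4, 7 or 14 or CPB 19 (adjusted p up to 0.0747). The immediate early call ended without control 1, 7, 10, 13 or 14 or CPB 2, 9 or 19 (up to 0.127). The mitochondrial gene ATP8 stood at 6270 CPM in CPB 21 and at 86.9 CPM or less in the other CPB hearts, and its call was lost without CPB 21. In the ileum of that animal it stood at 1300 CPM, and at 14.8 or less in the other ilea.

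In the kidney, CPB animals showed more transcripts of antioxidant enzymes, of keratins and other genes of injured tubules and of S100A10, and fewer of macrophage, fibroblast and some endothelial genes. HMOX1 (ENSSSCG00000039745), the enzyme that breaks down heme, rose by 4.23 ± 0.6 (adjusted p = 0.000129), from 106 ± 95 to 2000 ± 1330 CPM. KRT8 (ENSSSCG00000000252), a keratin of simple epithelia, rose by 1.88 ± 0.19 (adjusted p = 3.3e-06), from 152 ± 29.9 to 559 ± 179 CPM. S100A10 (ENSSSCG00000006612), which binds annexin A2 at the cell surface, rose by 1.43 ± 0.11 (adjusted p = 1.87e-07), from 165 ± 22.1 to 444 ± 32.1 CPM, with all 7 CPB kidneys above every control. Other large rises among named genes were those of the chemokine CCL27 (5.32 ± 0.73), the transcription factor FOSL1 (5.02 ± 0.72), the interleukin 33 receptor IL1RL1 (4.28 ± 0.72) and the hormone gene GUCA2B (4.07 ± 0.45, from 0.739 ± 0.883 to 12.4 ± 3.01 CPM).

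Of 16 NRF2 target and metallothionein genes in kidney, 9 rose, 0 fell and 7 did not pass, and 12 rose when adjusted over the list alone (list adjusted p = 2.75e-08, estimated 0.557). SRXN1, which repairs oxidized peroxiredoxins, rose by 2.55 ± 0.3 and the quinone reductase NQO1 by 1.81 ± 0.39. Of 17 tubular injury genes 7 rose and 0 fell, and 8 rose when adjusted over the list alone (list adjusted p = 0.00192, estimated 0.922), including KRT18 (1.93 ± 0.28) and SPP1, which encodes osteopontin (1.6 ± 0.32). The IL6-STAT3 list passed as well (7 of 19 rose, 0 fell, and 8 rose adjusted over the list alone; adjusted p = 0.00192, estimated 0.922), with the survival factor MCL1 among its members. Fibroblast and smooth muscle markers were lower, with 6 of 14 fallen, 0 risen and 8 fallen adjusted over the list alone (list adjusted p = 0.00192, estimated 0.922), as in ACTA2 (−1.38 ± 0.35). Monocyte and macrophage markers were lower too, with 9 of 19 fallen and 0 risen, and 10 fallen adjusted over the list alone (list adjusted p = 0.0147, estimated 0.922), but without control 15 the list did not pass (adjusted p = 0.0737).

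The type I interferon list had a median of −1.3 in kidney with 3 of 23 genes lower and 0 higher, and 0 past the threshold adjusted over the list alone (list adjusted p = 0.00192, estimated 0.922). Its IFIT2 stood at 327 CPM in control 15 and at 40.6 or less in the other controls. Epithelial junction genes passed weakly (5 of 16 rose, 0 fell, the same counts adjusted over the list alone; adjusted p = 0.041, estimated 0.922), with F11R (0.81 ± 0.14), CLDN7 (0.78 ± 0.17) and OCLN (0.52 ± 0.14). Immediate early genes did likewise (7 of 27 rose, 0 fell, the same counts adjusted over the list alone; adjusted p = 0.0339, estimated 0.922). The junction call ended without control 1, 4, 10, 15 or 26 or CPB 2, 11 or 25 (adjusted p up to 0.111). That of immediate early genes ended without control 4 or 10 or CPB 19 or 21 (up to 0.108). In lists that did not pass, EMCN, an endothelial surface protein, changed by −1.04 ± 0.12 (from 57.3 ± 5.21 to 27.7 ± 7.17 CPM), and the angiopoietin receptor TEK by −1.21 ± 0.33. The cell cycle inhibitor CDKN1A rose by 1.34 ± 0.29. The loop transporter SLC12A1 changed by −1.19 ± 0.33 and the clock genes TEF and DBP by −1.27 ± 0.28 and −1.19 ± 0.26. Fat cell genes differed between libraries: ADIPOQ had 0 counts in all 7 CPB kidneys and 23.6 ± 42.7 CPM in controls (median 0.3, highest 117 in control 26). Against a floor of 3 counts over the CPB group, 0.0134 CPM, it is at least 22.5-fold lower on the control median and 1760-fold on the control mean, which control 26 and control 1 (57.5 CPM) carry. Reads of a PCR library are not independent molecules, so this floor covers counting error only. PLIN1, which coats lipid droplets, stood at 7.76 ± 11.2 CPM in controls and 0.234 ± 0.176 in CPB, and limma-voom called neither gene.

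In the liver, genes of cholesterol synthesis fell together, many genes of the respiratory chain and some of the urea cycle rose, and some markers of lymphocytes and macrophages fell. SQLE (ENSSSCG00000005970), squalene epoxidase, changed by −3.52 ± 0.4 (adjusted p = 0.000107), from 77.1 ± 42.3 to 6.72 ± 2.07 CPM, with all 7 CPB livers below every control. Of 19 cholesterol synthesis genes 14 fell, 0 rose and 5 did not pass, the same counts as adjusted over the list alone (list adjusted p = 3.08e-08, estimated 0.854). HMGCS1 changed by −2.83 ± 0.42 (from 103 ± 62.3 to 14.5 ± 3.36 CPM), IDI1 by −2.57 ± 0.52 and MSMO1 by −2.51 ± 0.36. Arginase ARG1 (ENSSSCG00000004195), the last enzyme of the urea cycle, rose by 2.9 ± 0.62 (adjusted p = 0.00289), from 346 ± 554 CPM, or 152 ± 73.6 without control 4 (1710 CPM), to 2580 ± 1150.

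Of 8 urea cycle genes in liver 3 rose, 0 fell and 5 did not pass, and 4 rose when adjusted over the list alone (list adjusted p = 0.00653, estimated 0.854). The mitochondrial ornithine carrier SLC25A15 rose by 1.66 ± 0.32, from 88.4 ± 56.8 to 279 ± 50.4 CPM. Oxidative phosphorylation genes rose in 16 of 24 cases and fell in 0, and 19 rose adjusted over the list alone (list adjusted p = 8.37e-07, estimated 0.854), among them the complex III subunit UQCRB (0.89 ± 0.2) and the complex I subunits NDUFA5 (0.83 ± 0.15) and NDUFB5 (0.74 ± 0.18). Glucose-6-phosphatase G6PC1 rose by 1.81 ± 0.5. The deadenylase NOCT (ENSSSCG00000024596), also known as nocturnin, rose by 4.11 ± 0.66 (adjusted p = 0.000508), from 2.32 ± 1.36 to 40.4 ± 53.7 CPM, or 20.6 ± 11.7 without CPB 2 (160 CPM). CPT1A, which admits fatty acids to mitochondria, rose by 1.07 ± 0.28. The steroid-induced genes FKBP5 and PER1 rose by 1.73 ± 0.43 and 1.72 ± 0.4, and the bile salt export pump ABCB11 changed by −1.13 ± 0.25.

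Immune markers were lower in CPB livers. T and NK cell markers fell in 7 of 20 cases and rose in 0, with 10 lower adjusted over the list alone (list adjusted p = 0.000234). Monocyte and macrophage markers fell in 9 of 19 and rose in 1, the same counts adjusted over the list alone (adjusted p = 0.0021). B and plasma cell markers fell in 7 of 12 and rose in 0, the same counts adjusted over the list alone (adjusted p = 0.0156). All stood at adjusted p = 0.854 with an estimated correlation. Examples were the T and NK cell adhesion molecule CD2 (−1.44 ± 0.42), the macrophage receptors SIGLEC1 (−1.38 ± 0.25) and TIMD4 (−0.8 ± 0.17), and the B cell receptor partner CD22 (−1.46 ± 0.34). Transcripts typical of ileum, which holds many lymphocytes, made up a median of 0.468% of an ileal profile in control livers and 0.223% in CPB livers. Over 2049 genes high in ileum the change between these arms did not follow the one predicted from the share (slope −0.08, from −0.18 to 0.02, r = −0.0344), though 16.4% of the genes high in ileum were above 0 and 52.1% of the others. These genes were picked as low in CPB livers, which by itself draws their changes below 0. Neither value therefore decides whether ileal RNA plays a part. Interferon gamma genes fell in 6 of 21 cases (adjusted p = 0.0021) and type I interferon genes in 6 of 23 (adjusted p = 0.0183). So did NF-kB cytokine genes in 3 of 18 (adjusted p = 0.00683) and cell cycle genes in 5 of 20, with 1 higher (adjusted p = 0.0156). In all 4 lists the counts were the same adjusted over the list alone, and the estimated adjusted p was 0.854. IRF1, a regulator of interferon responses, changed by −1.23 ± 0.29, TNF by −1.34 ± 0.32 and thymidylate synthase TYMS by −1.21 ± 0.3. The type I interferon call ended without control 15 (adjusted p = 0.181), control 26 (0.111) or CPB 2 (0.121), and the cell cycle call without CPB 2 (0.0937) or CPB 6 (0.0851).

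In the lung, CPB animals had fewer transcripts of macrophage receptors and of the endothelial receptor KDR, lower interferon genes as lists, and more of some steroid-induced genes and neutrophil markers. TIMD4 (ENSSSCG00000017062), a receptor of resident macrophages, changed by −1.37 ± 0.2 (adjusted p = 0.00139), from 113 ± 33 to 43.6 ± 12.5 CPM, and SIGLEC1 changed by −1.35 ± 0.24. KDR (ENSSSCG00000008844), the main VEGF receptor of endothelium, changed by −0.9 ± 0.12 (adjusted p = 0.00125), from 443 ± 52.7 to 238 ± 49.5 CPM, and all 7 CPB lungs lay below every control. ATP12A (ENSSSCG00000022638), a proton pump, rose by 3.92 ± 0.49 (adjusted p = 0.000716), from 0.153 ± 0.104 to 2.43 ± 1.36 CPM, and the relaxin receptor RXFP1 changed by −2.4 ± 0.54.

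Of 19 monocyte and macrophage markers in lung 8 fell and 1 rose, and 11 fell and 1 rose adjusted over the list alone (list adjusted p = 4.93e-06, estimated 0.438). Glucocorticoid-responsive genes rose in 3 of 18 cases and fell in 0, with 12 higher adjusted over the list alone (list adjusted p = 4.72e-06, estimated 0.438), among them the phosphatase DUSP1 (1.08 ± 0.21) and the metallothionein MT1A (3.43 ± 0.61). Type I interferon genes had a median of −1.34, with 1 of 23 lower and 0 higher but 19 lower adjusted over the list alone (list adjusted p = 1.73e-08, estimated 0.444), as in IFIT2 (−1.63 ± 0.34). Interferon gamma genes had a median of −0.64, with 2 of 21 lower and 9 lower adjusted over the list alone (list adjusted p = 2.7e-06, estimated 0.444). Neutrophil markers rose in 4 of 14 cases and fell in 1, with 8 higher and 1 lower adjusted over the list alone (list adjusted p = 0.0196, estimated 0.444), including the alarmin S100A8 (1.71 ± 0.37). The NRF2 target list passed (3 of 16 rose, 0 fell, and 7 rose adjusted over the list alone; adjusted p = 0.000288, estimated 0.444). So did the unfolded protein list (3 of 23 rose, 0 fell, and 5 rose adjusted over the list alone; adjusted p = 0.00473, estimated 0.444).

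Lymphocyte and proliferation lists were lower in lung. B and plasma cell markers fell in 4 of 12 cases, with 6 lower adjusted over the list alone (list adjusted p = 0.000231, estimated 0.444), as in CD22 (−1.03 ± 0.18). T and NK cell markers had a median of −0.73 with 0 of 20 past the threshold and 6 lower adjusted over the list alone (list adjusted p = 2.12e-05, estimated 0.444). Cell cycle genes had a median of −0.54 with 0 of 20 past it and 2 lower adjusted over the list alone (list adjusted p = 0.000227, estimated 0.475). Cholesterol synthesis genes fell in 2 of 19 cases, 3 adjusted over the list alone (list adjusted p = 0.00121, estimated 0.475). Alveolar type 1 genes fell in 1 of 9 cases, 2 adjusted over the list alone (list adjusted p = 0.0107, estimated 0.444), as in RTKN2 (−1.2 ± 0.26). Kynurenine pathway genes fell in 2 of 12 cases, the same count adjusted over the list alone (list adjusted p = 0.0244, estimated 0.438). Epithelial junction genes rose in 1 of 16 cases, with 3 higher and 1 lower adjusted over the list alone (list adjusted p = 0.0213, estimated 0.444). Fibroblast and smooth muscle markers had a median of 0.39 with 0 of 14 past the threshold, 0 adjusted over the list alone (list adjusted p = 0.0275, estimated 0.543). The last call ended without control 15 or 26 or CPB 6, 11 or 21 (adjusted p up to 0.161). Kidney genes were present in some CPB lungs: UMOD, SLC22A8 and PCK1, which serve renal tubules, had log2 fold changes of 9.7 ± 2.23, 8.7 ± 1.93 and 7.17 ± 1.67, calls that were lost with limma-voom and without control 26. Renal transcripts made up 0.676% of a kidney profile in CPB 19, 0.492% in CPB 25 and 0.148% in CPB 21, and 0.369% and 0.167% in linrodostat animals 20 and 18, against 0.0457% or less in controls. A pair of unnamed genes took 21.7% of all counts in lung control 1 and 18.5% in lung CPB 25. The lung count of 840 genes became 189 without both of these libraries, 466 with the renal share and 205 with the ileal share as a covariate, and 1722 by DESeq2. It became 504, 473, 549 and 362 without control 1, 7, 10 or 26, 491, 1336, 551, 450 and 322 without CPB 2, 6, 11, 19 or 25.

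**Figure D2:**
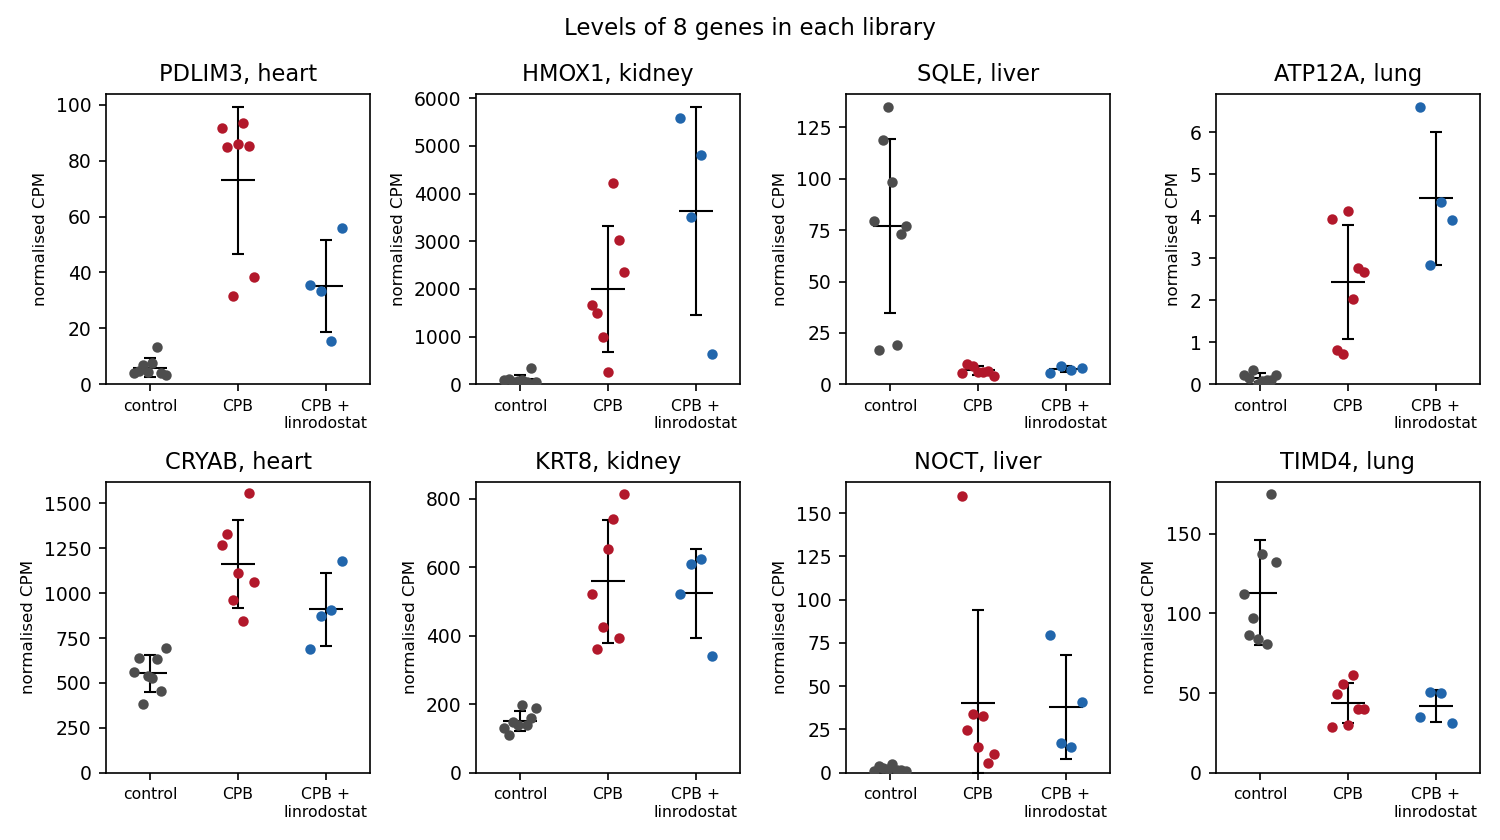
Normalised level in CPM (linear axis from 0) of 8 genes in single libraries (points), with the mean and SD of each arm (bars), for PDLIM3 and CRYAB in heart, HMOX1 and KRT8 in kidney, SQLE and NOCT in liver, and ATP12A and TIMD4 in lung. SQLE fell from a mean of 77.1 in control livers to 6.72 in CPB livers and 7.31 with linrodostat, and PDLIM3 rose from 5.92 to 73 and 35.1 in heart.

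In the ileum no single gene passed, and what follows are values of lists. Enterocyte genes, which serve nutrient uptake, had a median log2 fold change of −0.84 over 20 genes (list adjusted p = 1.44e-09, estimated 0.44). The ileum of CPB 19 lay apart, with an enterocyte score of −5.06 against −0.92 to 1.37 in the other CPB ilea. The mean score was 0.63 ± 0.68 in controls, −0.76 ± 2.04 in CPB and −0.04 ± 0.83 without CPB 19, and the list then passed at adjusted p = 7.16e-06. The ilea were of 2 kinds. In control 7, 13 and 14, CPB 2 and 19 and linrodostat animals 12 and 18 the B cell score was −1.12 or less and the muscle score 0.19 or more, and in the others the B cell score was 0.83 or more. The enterocyte score was 0.88 to 1.51 in the first kind, CPB 19 apart. Stem and secretory cell genes had a median of 0.61 over 16 (list adjusted p = 0.000175, estimated 0.512), of which 4 were higher adjusted over the list alone. The bile acid exporter SLC51A stood at 211 ± 109 CPM in controls and 78.4 ± 46.5 in CPB (−1.43 ± 0.44, adjusted p = 0.755). ATOH1, the factor that directs cells to the secretory fate, stood at 2.89 ± 0.604 and 9.62 ± 8.37 CPM (1.74 ± 0.46, adjusted p = 0.575), and AGR2, a disulfide isomerase of goblet cells, at 28.5 ± 10.2 and 75.7 ± 66.6 CPM (adjusted p = 0.659). NF-kB cytokine genes had a median of −0.35 (list adjusted p = 1.11e-06, estimated 0.41). Immediate early genes had a median of −0.24 (list adjusted p = 1.26e-05, estimated 0.41), of which 3 were lower adjusted over the list alone. JUNB, a partner in the AP-1 factor, stood at 220 ± 54.3 and 137 ± 22 CPM (−0.68 ± 0.16, adjusted p = 0.575).

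Cholesterol synthesis genes (median −0.29, adjusted p = 5.01e-05, estimated 0.512), interferon gamma genes (−0.21, adjusted p = 0.000157, estimated 0.54) and heat shock genes (−0.32, adjusted p = 0.00116, estimated 0.44) were also lower as lists in ileum, each with 0 genes adjusted over the list alone. The IL6-STAT3 list was lower (−0.32, adjusted p = 0.000368, estimated 0.44) with 4 of 19 genes lower adjusted over the list alone. Weaker list calls were those of type I interferon genes (−0.2, adjusted p = 0.0099, with 1 lower adjusted over the list alone), fibroblast and smooth muscle markers (0.22, adjusted p = 0.00151), endothelial cell markers (0.08, adjusted p = 0.0183) and endothelial activation genes (−0.25, adjusted p = 0.0242), with 0 genes adjusted over the list alone in the last 3. With an estimated correlation these stood at adjusted p = 0.739, 0.646, 0.739 and 0.57. The type I interferon call ended without control 14 or 15 or CPB 6 or 21 (adjusted p up to 0.244) and the fibroblast call without CPB 19 (0.0555). The endothelial marker call ended without control 1, 10 or 15 or CPB 19 or 21 (up to 0.228), and the activation call without control 13, 15 or 26 or CPB 2 or 9 (up to 0.219).

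The next question, named in the title of the series, was whether the response to CPB differed between organs. A test of equal CPB effects in the 5 organs called 2628 of 20321 genes, 3167 with the animal as a block, 1946 with the animal as a random effect, and 1700 without CPB 25. In simulated data 24 of 115 calls of this test were of unchanged genes, more than its threshold allows for. SQLE had the smallest interaction p (adjusted p = 8.32e-11), with log2 fold changes of −3.52 ± 0.4 in liver, 1.89 ± 0.52 in heart, 0.25 ± 0.28 in kidney, −0.06 ± 0.18 in ileum and −0.21 ± 0.15 in lung. Its call in heart was lost with limma-voom, with no low-count filter and without CPB 2. MSMO1 (interaction adjusted p = 9.29e-09) and HMGCS1 (1.7e-08), also of cholesterol synthesis, fell in liver and did not pass in the other organs. NOCT (interaction adjusted p = 3.02e-10) rose in liver and did not pass elsewhere. EHBP1, an endocytic adaptor, and the transcription factor RFX2 rose in heart by 2.35 and 2.78 (interaction adjusted p = 3.02e-10 and 5.88e-10). ATP12A rose in lung and changed by −2.05 ± 0.38 in kidney, from 43.9 ± 19.5 to 10.5 ± 6.34 CPM (interaction adjusted p = 8.14e-08). HMOX1 stood at 4.23 ± 0.6 in kidney, 2.12 ± 0.55 in heart, 1.04 ± 0.27 in liver, 1.38 ± 0.47 in ileum and 0.53 ± 0.26 in lung (interaction adjusted p = 0.000322), past the threshold in the first 3. In ileum CPB 19 stood at 315 CPM, and the CPB mean went from 83.1 to 44.5 without it, against 31.9 in controls.

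Pairwise, 1505 genes differed between ileum and liver, 1263 between heart and liver, 794 between liver and lung, and 716 between kidney and liver. There were 658 between heart and kidney, 643 between heart and ileum, 506 between ileum and kidney, 288 between heart and lung, 248 between kidney and lung and 53 between ileum and lung. All heart libraries bear batch label 2 and all others batch label 1, so batch and organ cannot be told apart for the heart, and without the heart 2015 genes passed. Across organs, 0 of 13637 genes tested in all 5 passed in the same direction in all 5, since ileum had none. In heart, kidney, liver and lung together 62 genes did (36 higher, 26 lower), against 0.721 for independent lists, and 49 of them had the same sign in ileum. They include, chosen after their values were seen, the antioxidant gene SRXN1, the phosphatase gene DUSP1, the transglutaminase gene TGM3 and the chaperone gene DNAJB9 among those that rose, and IFIT2 and STING1, a sensor of cytosolic DNA signals, among those that fell. Kidney and liver shared 1331 calls in the same direction (465 for independent lists) and 61 in opposite directions. The organs come from the same animals, whose kidney and liver libraries go together (median r 0.3, and −0.0108 between different animals), so independent lists understate the sharing to be had without an effect of CPB.

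The last question was whether linrodostat changed the response to CPB, or brought it back toward the controls. In the liver, animals given linrodostat had more transcripts of intestinal epithelium and of B cells than CPB animals. Of 119 liver genes that passed, 117 were higher and 2 lower. In ileum 113 of the 117 had at least 1 CPM and 10 times their level in CPB livers, as did 2064 (13.4%) of all 15406 tested genes. CPB livers are also the base of this comparison, which favours genes called higher. The brush border enzyme gene SI stood at 0.901 ± 0.55 CPM in CPB livers and 16 ± 12.2 with linrodostat (4.13 ± 0.76, adjusted p = 0.0124), and OLFM4, a crypt gene, at 1.14 ± 0.713 and 19.2 ± 10.1 (4.06 ± 0.83, adjusted p = 0.0235). Ileal transcripts made up a median of 1.6% of an ileal profile in the linrodostat livers (1.16 to 3.51%). It was 0.223% in CPB (0.0625 to 0.409%) and 0.468% in control (0.0349 to 0.968%). With that share as a covariate, an alternative added after the data were seen, 0 genes passed. The share separates these 2 arms and is made of ileal genes, so this does not tell ileal RNA from a drug effect. The count fell to 1 without linrodostat animal 18, to 74 without linrodostat animal 24, and to 71, 65, 73, 69 and 74 without CPB 2, 6, 11, 21 or 25.

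B and plasma cell markers rose in 3 of 12 cases in these livers, and in 7 adjusted over the list alone (list adjusted p = 6.58e-08, estimated 0.751). The 2 genes that fell were TARS3, a threonyl-tRNA synthetase (−1.08 ± 0.24), and EHD1, an endocytic recycling protein (−0.86 ± 0.19). Cell cycle genes had a median of 0.46 in liver with 0 past the threshold, 0 adjusted over the list alone (list adjusted p = 0.000497, estimated 0.884). Fibroblast and smooth muscle markers (median 0.3, adjusted p = 0.0204), coagulation genes (0.24, adjusted p = 0.0252), endothelial activation genes (0.49, adjusted p = 0.0252) and secreted plasma proteins (−0.15, adjusted p = 0.00724) passed as lists, each at adjusted p = 0.884 with an estimated correlation and with 1, 1, 1 and 0 genes past the threshold adjusted over the list alone. The fibroblast call ended without linrodostat animal 20 (adjusted p = 0.413) or 24. The coagulation call ended without CPB 6 or 21 or linrodostat animal 20 (0.121) or 24. The activation call ended without CPB 2 or 11 or linrodostat animal 18 (0.264) or 20, and the plasma protein call without linrodostat animal 20 (0.0747).

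**Figure D3:**
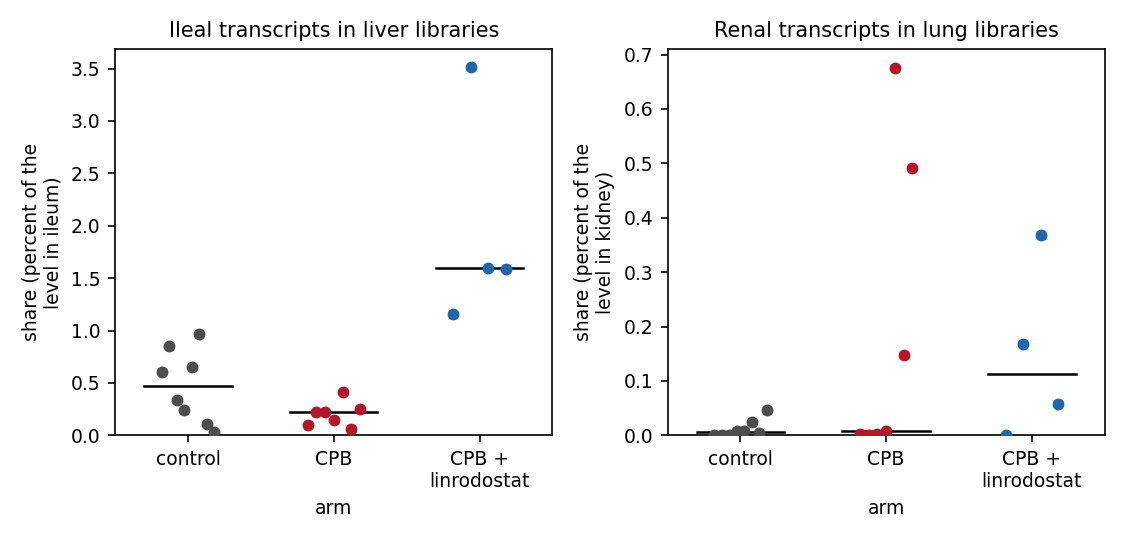
Transcripts of another organ as a percent of that organ's own profile in each library (points; horizontal lines are medians), with the ileal share in liver and the renal share in lung by arm. The 4 linrodostat livers lie between 1.16 and 3.51% and all CPB livers at 0.409% or less, and 3 CPB lungs stand at 0.148% or more.

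In heart, ileum, kidney and lung 0 genes passed between linrodostat and CPB with edgeR. An unadjusted p under 0.05 was found for 901, 1641, 822 and 462 of 14890, 17869, 17653 and 17849 genes. Chance alone gives about 0.05 of the tested genes, and kidney and lung lay below that. DESeq2 called 16, 86, 4 and 3 genes and limma-voom 0 in each. In the kidney, immediate early genes stood higher with linrodostat, with a median of 0.6 over 27 genes, 0 past the threshold and 6 higher adjusted over the list alone (list adjusted p = 1.46e-16, estimated 0.337), as in JUN (77.4 ± 18.9 and 142 ± 19.5 CPM, adjusted p = 0.955). Kidney IL6-STAT3 genes (median 0.5, adjusted p = 1.53e-09, estimated 0.337), fibroblast and smooth muscle markers (0.41, adjusted p = 6.84e-06, estimated 0.457), coagulation genes (0.28, adjusted p = 4e-05, estimated 0.337), cholesterol synthesis genes (0.35, adjusted p = 0.000266, estimated 0.457) and NRF2 targets (0.28, adjusted p = 0.00117, estimated 0.457) were higher as lists, with 0, 1, 1, 0 and 1 genes higher adjusted over the list alone. Kidney type I interferon genes were lower as a list (median −0.83, 0 genes adjusted over the list alone; adjusted p = 2.64e-06, estimated 0.533). Kidney linrodostat animal 12 held hepatocyte transcripts at 1.31% of a liver profile, and the acute phase list (0.78, adjusted p = 0.00326, estimated 0.457) ended without it (adjusted p = 0.66). The glucocorticoid list (0.2, adjusted p = 0.000266, estimated 0.457) ended without the same animal (0.128). The heat shock list (0.2, adjusted p = 0.000244, estimated 0.457) ended without it or linrodostat animal 18 (0.121). The tubular injury list (0.3, adjusted p = 0.00321, estimated 0.533) ended without CPB 6 or linrodostat animal 18 (0.216) or 20. The interferon gamma list (−0.25, adjusted p = 0.0287, estimated 0.815) ended without CPB 9, 19 or 21 or linrodostat animal 12, 20 or 24 (up to 0.673). The unfolded protein list (0.13, adjusted p = 0.0458, estimated 0.573) ended without CPB 6, 9, 11 or 21 or linrodostat animal 12 or 18 (up to 0.262). None of these 6 lists had a gene past the threshold adjusted over the list alone.

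In the heart, heat shock genes stood lower with linrodostat than with CPB alone (median −0.25, adjusted p = 0.000137, estimated 0.662), with 0 of 21 past the threshold and 2 lower adjusted over the list alone. HSPB1 stood at 958 ± 180 CPM in CPB and 583 ± 41.2 with linrodostat (−0.72 ± 0.14, adjusted p = 0.5), against 496 ± 41.9 in controls. Endothelial cell markers of the heart were higher as a list (0.43, 0 genes adjusted over the list alone; adjusted p = 6.51e-06, estimated 0.662) but not without linrodostat animal 12 (adjusted p = 0.0824). The fibroblast and smooth muscle call (0.27, adjusted p = 0.00784, estimated 0.662) ended without CPB 9 (0.104) or linrodostat animal 12. That list had 2 genes higher adjusted over the list alone. In lung, type I interferon genes were lower (median −0.64, adjusted p = 8.14e-09, estimated 0.641) and endothelial cell markers (0.24, adjusted p = 4.37e-05, estimated 0.306) and coagulation genes (0.19, adjusted p = 0.000727, estimated 0.28) higher as lists, each with 0 genes adjusted over the list alone. Aryl hydrocarbon receptor targets passed too (0.5, adjusted p = 0.0295, estimated 0.28), with the xenobiotic enzyme CYP1A1 at 9.04 ± 3.4 CPM in CPB and 26.5 ± 26.9 with linrodostat (adjusted p = 1), a call that ended without CPB 11 (0.0903) or linrodostat animal 12 or 20. Lung interferon gamma genes (−0.29, adjusted p = 1.27e-05, estimated 0.641) passed but not without linrodostat animal 24 (0.0619). Immediate early genes (0.16, adjusted p = 0.000609, estimated 0.641) passed but not without CPB 21 (0.054). The monocyte and macrophage (−0.15, adjusted p = 0.0295, estimated 0.767), alveolar type 1 (0.25, adjusted p = 0.0295, estimated 0.641) and erythroid and platelet (0.3, adjusted p = 0.0412, estimated 0.625) lists of the lung also passed. They ended without CPB 2, 9, 11 or 19 or linrodostat animal 18 or 24 (up to 0.645), without CPB 2, 9 or 25 or linrodostat animal 18 or 24 (up to 0.36), and without CPB 2, 11 or 21 or linrodostat animal 18 or 24 (up to 0.143). None of these lung lists had a gene past the threshold adjusted over the list alone. In ileum the oxidative phosphorylation list was higher (0.3, with 7 genes higher adjusted over the list alone; adjusted p = 2.1e-05, estimated 0.859) and the type I interferon (−0.55, adjusted p = 3.59e-05), immediate early (−0.34, adjusted p = 0.00437) and endothelial marker lists (−0.35, adjusted p = 0.000268) lower, all at adjusted p = 0.859 with an estimated correlation and with 0, 0 and 1 genes lower adjusted over the list alone. These 4 calls ended without linrodostat animal 24 (adjusted p = 0.281, 0.158, 0.123 and 0.166). The ileal enterocyte list passed too (0.62, adjusted p = 0.0353, estimated 0.859) and ended without CPB 19 or 25 or linrodostat animal 12, 18 or 20 (up to 0.563).

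Against the controls, the linrodostat arm gave 304 genes in heart, 38 in ileum, 3527 in kidney, 3358 in liver and 419 in lung. The heart count became 693 by DESeq2, 185, 190, 183 and 183 without control 7, 10, 14 or 15, and 153 and 75 without linrodostat animal 20 or 24. In kidney 2287 and 1901 passed without linrodostat animal 12 or 18, and in liver 1857 without linrodostat animal 24 and 594 with the ileal share as a covariate. The lung count became 1108 by DESeq2, 278 without a low-count filter, 232 without the 2 libraries named above, 122 with the ileal share as a covariate, 252, 254 and 230 without control 1, 7 or 26, and 165, 157 and 86 without linrodostat animal 12, 20 or 24. Of the main counts, 256 in heart, 2472 in kidney, 2367 in liver and 287 in lung had passed in the same direction with CPB alone, where independent lists would share 18.2, 377, 466 and 9.96, but both comparisons use the same controls. With the controls divided between them, the shared counts were 22 to 109, 984 to 1178, 884 to 1025 and 21 to 37, where independent lists would share at most 4.04, 191, 201 and 0.709. The ileal count of 38 became 818 by DESeq2, 72 with relative log expression size factors and 1428 with muscle and B cell scores as covariates. It became 0 without a low-count filter, with sex as a covariate, with only the 2 groups compared, or without linrodostat animal 20 or 24 or control 1, 4, 7, 10, 13, 15 or 26. It became 278 without linrodostat animal 12, 70 without control 14 and 14 without linrodostat animal 18. Across genes, which are not independent replicates, the log2 fold changes of linrodostat against CPB and of CPB against control had r = −0.471 in heart, −0.431 in ileum, −0.235 in liver, −0.175 in lung and −0.077 in kidney. The shared CPB libraries alone gave −0.439, −0.432, −0.431, −0.435 and −0.432 in simulated unchanged groups. Those groups hold no CPB effect, so their r is not on the scale of the measured r, and covariances are the closer comparison. The measured covariances were −0.137 in heart, −0.125 in ileum, −0.0812 in liver, −0.0385 in lung and −0.0225 in kidney. In the simulated groups they were −0.0736, −0.11, −0.0598, −0.067 and −0.0656. With the CPB animals split so that no library was shared, the mean r over 35 splits was −0.107, −0.00329, −0.0446, 0.179 and 0.101 in the same order of organs. Single splits gave −0.256 to 0.0582, −0.136 to 0.173, −0.218 to 0.196, −0.0984 to 0.425 and −0.0248 to 0.255. As these ranges hold 0 in each organ, the sign of r is not settled.

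IDO1 (ENSSSCG00000007007), the target of linrodostat, did not pass between any groups in any organ. It was most abundant in lung, at 98 ± 65.6 CPM in controls, 101 ± 97.5 in CPB and 89.9 ± 95.2 with linrodostat, and lay between 8.51 and 14.1 CPM in ileum and at 2.5 CPM or less in the other organs. Further along the kynurenine pathway, KYNU changed by −1.08 ± 0.27 and HAAO by −1.15 ± 0.22 in CPB livers, and KYNU by −0.79 ± 0.21 in lung. In kidney KMO changed by −0.48 ± 0.14 and IDO2 rose by 1.52 ± 0.25, from 23.4 ± 9.59 to 67.1 ± 18 CPM. The lung KYNU call was lost in 9 of the alternative settings. The cold-induced RNA-binding gene RBM3 (ENSSSCG00000021591) rose by 0.97 ± 0.24 in heart (adjusted p = 0.0107) and 1.42 ± 0.34 in liver (adjusted p = 0.00564), and stood at 0.82 ± 0.3 in kidney (adjusted p = 0.0596), 0.67 ± 0.27 in lung (adjusted p = 0.156) and 0.4 ± 0.38 in ileum (adjusted p = 1). Its effects did not differ detectably between organs (interaction adjusted p = 0.537). CIRBP, the other cold-induced gene followed, did not pass in any organ, with log2 fold changes of 0.3, 0.12, 0.13, 0.13 and 0.3 in heart, ileum, kidney, liver and lung.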

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

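The tests of the 3 patterns weighed below and the bounds for the random groupings were written after the result was seen, while the test of the interaction was fixed before.

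Liver libraries of the linrodostat arm held transcripts of intestinal epithelium, and ileal RNA or reads may be the source: over 2049 genes high in ileum, with the markers left out, the measured log2 fold change followed the change predicted from the ileal share with a slope of 0.99 (0.96 to 1.02). Across 9 livers of females, the share followed counts of 2 Y-linked genes with r = 0.905 (exact permutation p = 0.0113; rho = 0.752, exact p = 0.0247; r = 0.665 without linrodostat 18 and 20), which male tissue or reads of another library would bring. But linrodostat 18 and 20 also had 8 and 4 such counts in kidney, and 0 in their own ileum. These counts are thus not particular to liver and do not show RNA of the animal's own ileum. A drug effect on single liver genes would not be set by their level in ileum. But the genes were picked as low in CPB livers, whose level also enters the prediction and the measured change. Part of the slope and of the r of 0.82 is thus built in, and the interval takes genes as independent. These values therefore do not decide against a drug effect. In CPM without TMM, the share predicts 64.9 of FABP6, 47.4 of SPAI-2 and 150 of ANPEP in these livers, where 58.8 ± 39, 53.8 ± 22.3 and 128 ± 33.6 (SD, n = 4) were measured. It also predicts 203 of IGHM (131 ± 57.4 measured) and 94.4 of the muscle gene MYH11 (42.5 ± 17.6), or 81 from each animal's own ileum. MYH11 is 1 gene, and fibroblast and smooth muscle markers were higher as a list in these livers. Its gap therefore does not decide which layers of the ileal wall took part. With the share as a covariate the median of the 117 higher genes went from 3.13 (SE 0.64) to 0.86 (SE 0.65) and 0 passed. That share is made of ileal marker genes, SI and OLFM4 among them, and separates linrodostat from CPB livers without overlap. Genes raised by the drug along with the markers would lose their calls too, so this drop decides for neither account. The part of the ileum and the step at which its RNA may have entered stay open.

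Renal transcripts in lungs, highest in CPB 19 (0.676% of the kidney level), CPB 25 (0.492%), linrodostat 20 (0.369%) and linrodostat 18 (0.167%), may likewise come from kidney RNA or reads, since 441 genes high in kidney followed the prediction with a slope of 1.26 (1.16 to 1.36). Induction of renal genes in lung would not be proportional to a kidney profile. But the genes were picked as low in control lungs, whose level also enters the prediction and the measured change. Part of the slope and of the r of 0.772 is thus built in, and they do not decide against induction. Of abundant kidney genes, UMOD (12.7 ± 21.3 CPM without TMM measured in CPB lungs, SD, n = 7; 11.3 predicted) and PCK1 (2.61 ± 4.16 and 5.41) can be compared, while GPX3 (838 ± 424 and 521) and SPP1 (33.6 ± 13.8 and 78.4) are expressed in control lungs (499 ± 191 and 76.4 ± 139) at levels that hide the share. The 34 higher genes of this kind went from a median of 3.49 (SE 0.68) to 0.94 (SE 0.61) with the renal share as a covariate, of which 5 passed, and the other 806 called genes went from −0.44 (SE 0.16) to −0.39 (SE 0.16), of which 380 passed. The share is made of renal marker genes, so genes induced in lung along with them would shrink too, and this drop does not decide the source. The route of the RNA stays open.

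Interferon genes were lower as lists in CPB than in control animals in several organs. Most of their genes did not pass singly, and with an estimated correlation 0 lists passed in any organ. The type I score moved with the animal across heart, kidney, liver and lung (r between these organs 0.871 to 0.964, ileum not included). The mean score per animal was −0.29 ± 0.86 (SD, n = 7) in CPB and 0.7 ± 1.15 (SD, n = 8) in control (exact permutation p = 0.0824), and without control 15, which had the highest score, the exact permutation p was 0.145. An effect of the procedure and a difference between animals that was there before surgery (an infection of single controls, for example) could each give this. They cannot be told apart, because no sample was taken before surgery.

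Whether a random division of the animals can give each count was asked with 40 groupings, the real one included. Only the real grouping reached the count for CPB against control in heart (1775 genes, highest other grouping 3), kidney (3733, 159), liver (4151, 4) and lung (840, 307). The same holds for linrodostat against control in heart (304, 9), kidney (3527, 2), liver (3358, 223) and lung (419, 1), and for the genes shared by 4 organs (62, 0). With the real grouping among the 40, the smallest share this test can give is 1 of 40, so it does not exclude chance. For the interaction (2628, 188 over 24 groupings) the real grouping alone reached the count as well. But regrouping whole animals removes the CPB effect from every organ, so it does not test whether that effect differs between organs. Other groupings did reach the count for the CPB lists in heart (8, 15; 18 of 40), ileum (12, 17; 20 of 40), kidney (8, 20; 26 of 40) and liver (10, 18; 15 of 40), so chance cannot be excluded there. Nor can it for the lung lists (15, 14; 1 of 40), where the margin is narrow. For linrodostat against CPB it cannot be excluded in liver (119 genes, 602; 3 of 40), for its lists in heart (3, 16; 37 of 40), ileum (5, 18; 39 of 40), kidney (13, 19; 11 of 40), liver (6, 18; 28 of 40) and lung (9, 20; 28 of 40), or for linrodostat against control in ileum (38, 4967; 2 of 40). For liver the grouping with 602 genes and for ileum against control the one with 4967 call several times the real count, which points to a structure of the samples. Which structure was not tested. Where the real count is 0, all 40 of 40 groupings reach it, so the test says nothing there. The highest other counts were 1 for CPB in ileum, 0 for genes shared by 5 organs, and 595, 0, 56 and 57 for linrodostat against CPB in heart, ileum, kidney and lung.

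The test of equal CPB effects in the organs called 2628 genes, and in simulated data 24 of 115 of its calls were of unchanged genes. Among those called were SQLE (interaction adjusted p = 8.32e-11), TANGO2, NOCT and EHBP1 (3.02e-10 each), RFX2 (5.88e-10), MSMO1 (9.29e-09), HMGCS1 (1.7e-08), ATP12A (8.14e-08), TPD52L2 (1.19e-07) and HMOX1 (0.000322).

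In 59 of 750 groups 1 library lay far from the others, where chance gives about 1 in 20 groups, or 37.5. Total counts, in units of 1e6, were 53.6 in lung control 7 (others 32.6 to 41.1) and 42.7 in lung linrodostat 18 (others 34.8 to 36.1). A pair of unnamed genes took 21.7% of lung control 1 (others up to 1.65%) and 18.5% of lung CPB 25 (others up to 0.675%). The type I interferon score of liver CPB 2 was −1.99, and the glucocorticoid scores of ileum and kidney CPB 2 were 1.19 and 0.903.

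The values that follow are in normalised CPM. Below the others of the arm were RCOR2, LRP2 and RTKN2 in control 15, and IFIT2, TIMD4 and CD79B in CPB 2. So were CIRBP, RBM3 and STARD4 in CPB 9, CALB1 in CPB 19, and S100A10, BBC3, VWF and CD27 in CPB 11. ACTA2 in CPB 6, PHACTR3 in control 26, TRIB3 in control 4 and ACOXL in control 13 were low too. The rest were above. UMOD, SLC22A8 and PCK1 in lung control 26 rest on 4, 1 and 5 counts. In control 15, IDO1 was 7.9 in kidney and 7.28 in liver, and HMOX1 34.2, IRF1 82.2 and RCOR2 10.1 in heart. Its kidney had CIITA 89.3, OASL 26.1, IFIT2 327, TIMD4 11 and LRP2 376, its liver OASL 55.4, and its lung CXCL8 8.67 and RTKN2 40. ATP8 in CPB 21 was 6270 in heart, 2970 in kidney, 673 in liver and 761 in lung, and it stood at 1300 in the ileum of that animal (14.8 or less in the other ilea). CPB 2 had IFIT2 4.28 and TIMD4 0.0424 in kidney and SDS 1540, FKBP5 517 and CD79B 0.19 in liver. CPB 9 had CIRBP 186 in lung, RBM3 108 and HSPB1 139 in liver, and STARD4 4.01 in heart. CPB 19 had S100A2 25.2 and DNAJB9 35.3 in heart, CALB1 217 in kidney and PLAT 20.2 in liver. CPB 11 had S100A10 378 in kidney and BBC3 0.304, VWF (a gene that the gene ID table calls ANO2) 10 and CD27 0.169 in liver, CPB 6 had ACTA2 46.7 in kidney, and CPB 25 had MCM5 9.52 and CPT1A 360 in liver. Control 26 had PHACTR3 0.333 in heart, GUCA2B 2.89 in kidney, and UMOD 0.0961, SLC22A8 0.024 and PCK1 0.12 in lung. Control 10 had PLN 752 in heart and CACYBP 53.2 in liver, control 4 had TRIB3 0.408 in kidney and KMO 150 and ARG1 1710 in liver, control 14 had PFKFB3 106 in kidney, and control 13 had ACOXL 0.239 in lung. Linrodostat 18 had CD79B 5.17 in liver and linrodostat 24 had TDO2 0.156 in ileum.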

How the results depend on the processing

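The alternatives with covariates other than sex, left-out genes or library pairs, and shared calls in 4 organs were chosen after the data were seen, and the others were fixed before. Among counts and correlations that answer a comparison, 132 planned values stayed the same, 15 were higher, 24 lower, 4 moved and 2 turned. A count was the same within 1.5 times. A correlation was the same if it kept its sign and lay within the SD over splits of the CPB animals. Of 300 named calls, DESeq2 kept 292, limma-voom 244, no low-count filter 237 and relative log expression (RLE) size factors 296, and all 89 list calls were kept with RLE. The cause was not tested for the values below.

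With an estimated correlation 0 lists passed in each organ for CPB and for linrodostat. With fry 5, 0, 1, 4 and 4 lists passed for CPB in heart, ileum, kidney, liver and lung and 0 for linrodostat in each. DESeq2 called 16 genes in ileum and 1722 in lung for CPB, 16, 86, 4, 208 and 3 in heart, ileum, kidney, liver and lung for linrodostat against CPB, and 693, 818 and 1108 in heart, ileum and lung for linrodostat against control. For linrodostat against control in ileum, RLE gave 72 genes, no low-count filter, sex as a covariate and only the 2 groups compared gave 0 each, and smooth muscle and B cell scores gave 1428. No low-count filter gave 278 genes in lung for linrodostat against control, and 5 and 11 lists in heart and ileum for linrodostat against CPB. Only the 2 groups compared gave 6 lists in heart and RLE 8 in ileum, and the scores gave 3 lists in ileum. The ileal share as a covariate gave 205 genes for CPB in lung, 0 for linrodostat against CPB in liver, and 594 and 122 for linrodostat against control in liver and lung. The renal share gave 466 for CPB in lung. Without the 2 lung libraries, CPB gave 189 genes and linrodostat against control 232. Without genes high in ileum, linrodostat against CPB in liver gave 0 genes and 1 list. In 4 organs 62 genes were shared. The animal as a replicate block raised the interaction count to 3167, and limma-voom with the animal as a random effect gave 1946.

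The r between linrodostat and CPB effects, as a mean over splits of the CPB animals, moved from −0.471 to −0.107 in heart, −0.431 to −0.00329 in ileum and −0.235 to −0.0446 in liver, and turned to 0.101 in kidney and 0.179 in lung. Single splits lay on both sides of 0 in each organ. Over genes called with CPB it was −0.68 in heart, −0.141 in kidney, −0.254 in liver and −0.262 in lung, but these genes were chosen on the CPB effect and share its libraries, so a negative r there shows nothing by itself. With the ileal share as a covariate, the fibroblast (adjusted p = 0.817) and plasma protein lists (adjusted p = 1) of the linrodostat livers turned direction.

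With 1 animal left out, CPB gave 1257 to 2432 genes in heart, 0 to 0 in ileum, 2881 to 3853 in kidney, 3094 to 4570 in liver and 322 to 1336 in lung. Linrodostat against CPB gave 0 to 0 in heart, ileum and lung, 0 to 1 in kidney and 1 to 137 in liver, and linrodostat against control 75 to 293 in heart, 0 to 278 in ileum, 1901 to 3734 in kidney, 1857 to 3360 in liver and 86 to 536 in lung. The interaction gave 1700 to 2959, and 0 genes were shared by 5 organs each time. Lists passing for CPB were 7 to 10, 10 to 14, 6 to 11, 8 to 12 and 15 to 18 in heart, ileum, kidney, liver and lung, and for linrodostat against CPB 2 to 11, 3 to 11, 9 to 15, 5 to 10 and 7 to 12. Named calls kept were 234 to 298 of 300. In simulated data 20.3% of 2-fold changes were recovered in ileum and 58.7 to 70.4% in the other organs for CPB, which limits what a count of 0 can show.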

Other observations

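All tests in this part were chosen after the data were seen.

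Mean scores per animal over 4 organs (heart, kidney, liver and lung) were compared for 4 lists, in 12 tests. The IL6-STAT3 score was 0.26 ± 0.2 (SD, n = 4) with linrodostat, 0.04 ± 0.19 (SD, n = 7) in CPB and −0.16 ± 0.14 (SD, n = 8) in controls. Linrodostat differed from control by 0.42 (exact permutation p = 0.00202, adjusted p = 0.0242) and CPB from control by 0.2 (exact permutation p = 0.037, adjusted p = 0.103). Linrodostat against CPB, the test of the drug, gave 0.22 (exact permutation p = 0.112, adjusted p = 0.168). The glucocorticoid score differed by 0.69 between linrodostat and control (exact permutation p = 0.0141, adjusted p = 0.0846) by 0.45 between CPB and control (exact permutation p = 0.0449, adjusted p = 0.103) and by 0.23 between linrodostat and CPB (exact permutation p = 0.464, adjusted p = 0.506).

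A hypothesis was that animals with higher glucocorticoid-responsive genes had lower interferon genes, as steroid signalling may damp interferon responses. Over 19 animals the type I interferon and glucocorticoid scores had Pearson r = −0.584 (permutation p = 0.00916, adjusted p = 0.0275 over 6 relations) and Spearman rho = −0.249 (permutation p = 0.303). Without control 15 and CPB 2 r was −0.242, so the relation rests on those animals. Within controls r was −0.421 (exact permutation p = 0.302) and within CPB animals −0.388 (exact permutation p = 0.382), with rho of −0.119 and 0.0714. Without the 2 farthest animals of each arm these r turned to 0.558 and 0.733, so neither arm by itself shows an inverse relation. The glucocorticoid and heat shock scores had r = 0.655 (permutation p = 0.00193, adjusted p = 0.0116) and rho = 0.611 (permutation p = 0.00639) over 19 animals, and r = 0.487 without linrodostat 12 and CPB 2, but within controls r was 0.0967 (exact permutation p = 0.818) and within CPB animals 0.714 (exact permutation p = 0.0679), or 0.06 without CPB 2 and 9.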
